A study of Mus musculus with 2 samples.

How the data were processed

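H3K4me3 was immunoprecipitated from limb tissue of B6NCrl mouse embryos at embryonic day 12.5 and sequenced, in 2 libraries that the labels number as biological replicates 1 and 2, each a separate pool of embryos of both sexes. The analysis started from 4 peak lists that the authors deposited: 1 per replicate, 1 called on both replicates together, and 1 described as replicated, which per the deposited readme derives from the other 3. Each list was called with a control, per the readme. The build is mm10, per the labels. The read aligner, the peak caller, their versions, the calling threshold and the rule for the replicated list are not given in the sources used here. Signal tracks and reads were not analysed here.

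The value used per peak is the fold over background that the authors deposited, a linear ratio at the peak's summit. The lists also carry the authors' −log10 p and −log10 q per peak, of which the −log10 q was used to rank and filter peaks and the −log10 p only to check the background described below. A display score that the authors scaled for genome browsers was not used. The lowest −log10 q was 0.193 in replicate 1, 0.197 in replicate 2 and 0.727 in the replicated list, so the lists as deposited hold weak peaks. Fold values are the authors' own, depend on each list's depth, and were compared only within a list. Tests of fold between gene lists, chosen after the data were examined, are given in the closing section. The replicates' folds were compared by correlation across genes. The folds of the strongest peaks lay on steps equal to 1 added read over the background plus 1, and that step gives the background pile-up: 3.19 reads in replicate 1, 2.68 in replicate 2 and 5.79 in the pooled list. Among the strongest peaks 97.8%, 87.3% and 94.8% fell on such a step within 0.02 reads, but of all peaks 68.3%, 51.5% and 61.5% did. A step set in advance would catch 4% by chance. Here the step was fitted to the strongest peaks themselves, so 4% is too low a chance level for them. For the peaks on a step, the −log10 p computed from this background lay within 0.1 of the deposited one in 83.4% of replicate 1 and 83.2% of replicate 2. The depth in reads per library is otherwise unknown, and no counting interval can be given. Where a peak lay on the step, one read more or less at its summit moved the fold by 0.238 in replicate 1 and 0.271 in replicate 2.

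Peaks on chromosomes 1 to 19, X and Y were kept, which left out 13 peaks of replicate 1, 15 of replicate 2 and 12 of the replicated list on unplaced sequences. Overlaps, merges and the Jaccard index were computed in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and checked against bedtools 2.31.1 on simulated intervals. Genes came from GENCODE on GRCm38, the same assembly as mm10: 21938 protein-coding genes with 93513 start sites. A promoter is the 1 kb either side of any annotated start site of a protein-coding gene, and a gene was called marked if a peak overlapped a promoter by at least 1 bp. Where neighbouring genes share a promoter window a peak counts for each; 18256 genes had windows free of other genes. Domains are runs of peaks joined across gaps of at most 1 kb, and a gene's width is that of its widest promoter domain. A start site was CpG-rich when the 500 bp either side had a CpG observed over expected ratio of at least 0.6 and at least 50% GC. Coordinates are 1-based.

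There is 1 group of 2 replicates, so no groups of samples were compared, and replicate values are given as the mean ± SD (n = 2). All tests compare sets of genes within these libraries, and their p-values do not measure variation between embryos. Gene lists were fixed before the data were examined: 19 lists with 438 named entries, of which 1 symbol was not found in the annotation, and 7 families taken by symbol. Marking of each list was tested against all other protein-coding genes with Fisher's exact test, two-sided. Width was tested against 10000 random lists of the same size drawn from marked genes, two-sided, for lists with at least 5 marked members. Adjusted p-values follow Benjamini and Hochberg over the 26 lists tested for marking and the 20 tested for width, with 0.05 as the threshold. Stratified tests used the exact conditional form of the Cochran-Mantel-Haenszel test over CpG-rich and other genes. Genes of a cluster, or sharing a promoter, are not independent, so these p-values are too small for the Hox lists in particular.

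Genes named in the text were set before the data were examined by a rule with 5 parts: 27 marker genes of limb, cartilage, muscle, ectoderm, vessel, nerve, liver, heart and brain; protein-coding genes at the 10 widest domains; the 5 promoters with the highest fold; for each list past the threshold the 2 widest marked members and the first 2 unmarked ones in alphabetical order; and the 3 widest domains without a protein-coding start site. Tbx3, Ptch1, Wnt5a, Sympk and the noncoding genes in the closing section were named after their values were seen. Alternatives changed the peak list (each replicate alone, the pooled list), the minimum −log10 q (2 or 5), the overlap rule, the promoter window (500 bp or 2 kb), the start sites (1 per gene), the gap, the background genes and the CpG limits. On simulated lists of 25 genes over the same 21938 genes, the marking test called 100% of 10 raised lists, 90% of 10 lowered lists and 0% of 10 random ones. The width test called 80% of 10 lists planted 2-fold wider, 100% of 10 planted 2-fold narrower and 0% of 10 random ones. On 10 simulated lists of 100 genes drawn from CpG-rich genes with no other effect, the plain test called 100% and the stratified test 0%. Marking in this simulation depended only on the same CpG class, so it cannot show what CpG differences within a class would do.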

Results

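Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark found at the start sites of active and poised genes, was mapped by chromatin immunoprecipitation and sequencing in mouse limbs at embryonic day 12.5. At this age the limb bud carries digit rays, condensing cartilage, migrating muscle precursors, ingrowing vessels and nerves, and a covering ectoderm. The series held 1 group with 2 biological replicates, each a pool of limbs from embryos of both sexes: 88 embryos in replicate 1 and 68 in replicate 2. No second tissue, stage or treatment was part of the series, so the comparisons below are between replicates, between gene groups and between chromosome classes within the same limb chromatin. On chromosomes 1 to 19, X and Y the authors called 31523 peaks in replicate 1 and 31021 in replicate 2 (31272 ± 355, SD, n = 2). The peaks covered 37.9 and 38.0 Mb, or 1.39% ± 0.00228 of the assembly (SD, n = 2). The authors also deposited a list called on both replicates together, with 33930 peaks over 42.5 Mb, and a replicated list, with 24828 peaks over 40.1 Mb. Read totals are not part of the lists. The local background behind the strongest peaks, read back from the steps in the fold values, was about 3.19 reads in replicate 1 and 2.68 in replicate 2, a ratio of 1.19.

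The first question was how far the replicates marked the same places. Start sites of protein-coding genes were called alike in both: 14620 genes had a promoter peak in each replicate, 7060 in neither, and 258 in only 1, so that 98.8% of genes had the same call. Across the 14620 genes the fold of the strongest promoter peak correlated between replicates with a Spearman rho of 0.902 and a Pearson r of 0.930. The log2 width of the promoter domain correlated with a rho of 0.918 and an r of 0.926. These 4 values come from 2 measures in the same genes, each with a permutation p of 1e-05, the smallest that 100000 permutations can give, and genes are not independent replicates. Among all peaks, 80.1% of those in replicate 1 overlapped a peak of replicate 2 by at least 1 bp, and 81.6% of those in replicate 2 overlapped a peak of replicate 1. The Jaccard index over bases was 0.808. Peaks at protein-coding start sites were shared in 91.9% of cases in replicate 1 and 92.8% in replicate 2, against 65.6% and 67.4% of the peaks elsewhere. Sharing followed peak strength. With each list ranked by q and divided into 10 equal classes, all peaks of the 4 strongest classes were shared in either list, while in the weakest class 29.7% of replicate 1 and 33.6% of replicate 2 were. Unshared peaks had a median fold over background of 2.86 in replicate 1 and 2.99 in replicate 2, against 19.8 and 20.5 for shared peaks. With 2 libraries there is no test of the difference between replicates.

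**Figure D1:**
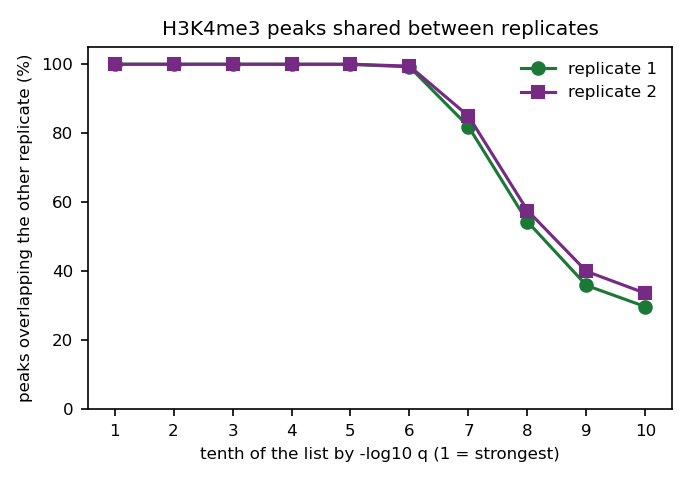
Share of H3K4me3 peaks that overlap a peak of the other replicate by at least 1 bp (y axis, percent), for 10 equal classes of a replicate's peaks ranked by the authors' −log10 q (x axis, 1 is the strongest); circles are replicate 1 and squares replicate 2. Both lines stay at or above 99.2% over the 6 strongest classes and end at 29.7% and 33.6%.

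The authors' replicated list was used for gene-level results. All of its 24828 peaks were identical in position to a peak of the pooled list, and 93.6% overlapped a peak of each replicate by at least 50% of either peak. Another 1514 peaks met that overlap in 1 replicate only and 84 in neither, so presence in both replicate lists was not required of every peak. The 1598 peaks of these classes had a median fold of 3.09, against 23.9 for the whole list. Promoters of 2 of the genes fixed in advance rest on weak peaks of this kind: Myog, a late muscle regulator, had a promoter peak in replicate 2 and none in replicate 1, and Cdh5, the endothelial cadherin, had none in either replicate, while the replicated list held peaks of 3.24-fold at Myog and 3.38-fold at Cdh5.

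H3K4me3 lay mostly at gene starts. In the replicated list 15601 peaks (62.8%) touched the 1 kb either side of a protein-coding start site, and these held 81.8% of the covered bases. A further 5.57% of peaks lay at start sites of other gene types, 6.02% in exons, 11.1% in introns and 14.5% between genes. Peaks at protein-coding start sites had a median width of 1952 bp and a median fold of 46.2. Intronic peaks had medians of 530 bp and 3.97-fold. In the replicate lists, which hold more weak peaks, 55.5% ± 0.533 of peaks lay at protein-coding start sites (SD, n = 2). A promoter peak was found at 14676 of 21938 protein-coding genes, or 66.9%. The replicates on their own gave 67.2% ± 0.0967 (SD, n = 2).

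The widest H3K4me3 domains of the limb covered the HoxA and HoxD clusters, which hold the homeobox genes that pattern the limb along its length. A domain was a run of peaks with gaps of at most 1 kb. The first, on chromosome 6 from 52202399 to 52267073, spanned 64.7 kb without a larger break and covered start sites of Hoxa5, Hoxa6, Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13, with distal start sites annotated to Hoxa3 and to the read-through gene Gm28308. It measured 65.4 ± 0.764 kb in the replicates (SD, n = 2). The second, on chromosome 2 from 74653803 to 74702388, spanned 48.6 kb over Evx2, Hoxd13, Hoxd12, Hoxd11, Hoxd10 and Hoxd9, and measured 47.9 ± 0.761 kb in the replicates (SD, n = 2). Peaks covered 71.2% of the HoxA cluster and 52.1% of HoxD, compared with 47.7% of HoxC and 29.2% of HoxB without Hoxb13. In each replicate list the order was the same, with 67.6% and 68.8% of HoxA and 23.9% and 26.3% of HoxB covered. The third domain, on chromosome 15 from 102953484 to 102984005, joined Hoxc11, Hoxc10, Hoxc9 and a start site of Hoxc5 over 30.5 kb in the replicated list. It was broken up in the replicates, where the widest overlapping domain measured 15.9 ± 2.01 kb (SD, n = 2).

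**Figure D2:**
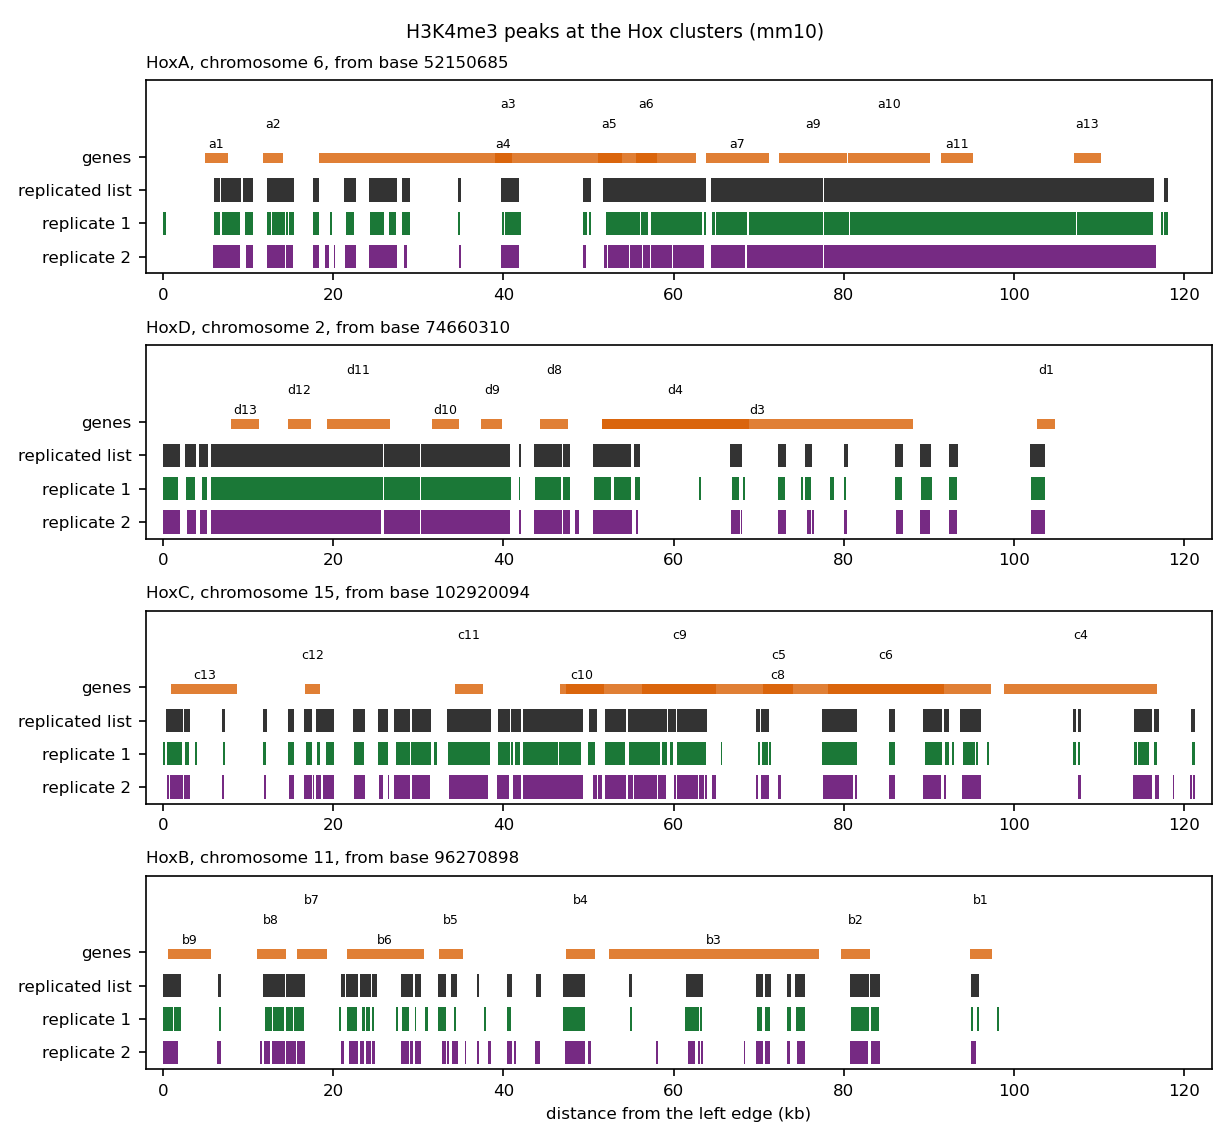
Maps of the HoxA, HoxD, HoxC and HoxB clusters (mm10, x axis in kb from the left edge of each panel, all panels to the same scale; Hoxb13 lies outside the HoxB panel). Orange bars are protein-coding genes and the black, green and purple bars are H3K4me3 peaks of the replicated list, replicate 1 and replicate 2. Peaks run together from Hoxa5 to beyond Hoxa13 and across Hoxd9 to Hoxd13, with 71.2% of HoxA and 29.2% of HoxB covered.

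The remaining domains among the 10 widest were centred on single genes, most of them genes of transcription factors. Nr2f2, an orphan nuclear receptor gene, lay in a domain of 25.04 kb (19.7 ± 4.72 kb in the replicates, SD, n = 2). Hand2, which sets up the posterior limb bud, lay in 23.3 kb on chromosome 8 from 57311985 to 57335319 (20.0 ± 0.697 kb, SD, n = 2). Lmx1b, required for dorsal limb identity, lay in 18.1 kb (18.0 ± 0.300 kb, SD, n = 2). Ebf3 lay in 17.4 kb (18.6 ± 2.10 kb), Tbx5, required for forelimb outgrowth, in 17.3 kb (17.1 ± 0.146 kb), and Tbx2 in 16.4 kb (16.2 ± 0.185 kb; SD, n = 2 in each). Midn lay in 17.8 kb, and the widest overlapping domain of each replicate measured 13.6 ± 4.37 kb (SD, n = 2).

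Genes of limb patterning and signalling were all marked. All 58 members of this list had a promoter peak, in the replicated list and in both replicates, against 66.8% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 3.32e-10 over 26 lists). Their domains had a median width of 7.20 kb, while random lists of marked genes had a median of 2.27 kb. The hindlimb regulators Pitx1 and Tbx4 lay in domains of 13.8 and 12.6 kb (13.7 ± 0.0113 and 12.9 ± 0.441 kb in the replicates, SD, n = 2). Prrx1, a marker of limb mesenchyme, lay in 10.5 kb with a fold of 70.3, and Gli3, which transduces hedgehog signals, in 7.14 kb with a fold of 72.9. The 4 signalling genes among the marker genes named by rule had narrower domains and lower folds than these. Shh, expressed in the posterior polarizing region, had a domain of 3.19 kb (3.70 ± 0.737 kb, SD, n = 2) and a fold of 11.8. Fgf8, of the apical ridge, had 3.71 kb and 28.6-fold. Fgf10 had 4.30 kb and 35.5-fold, and the BMP antagonist Grem1 had 3.18 kb and 37.8-fold. Narrow domains did not extend to all signalling genes of the list. Ptch1 lay in 13.3 kb and Wnt5a in 12.3 kb, both named after their values were seen. All 20 HoxA and HoxD genes and all 19 HoxB and HoxC genes were also marked (adjusted p = 0.00102 and 0.00166, Fisher's exact test).

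Lists of cell types present in the limb gave a mixed picture. Of 29 chondrogenic genes, 26 were marked (exact test, adjusted p = 0.0129, Fisher's exact test), among them Sox9, the master regulator of cartilage, with 7.13 kb, Col2a1, a main cartilage collagen, with 6.56 kb, Wwp2 with 11.8 kb and Sox6 with 11.3 kb. The Wwp2 domain, on chromosome 8 from 107544955 to 107556766, did not lie at the 5' end of the gene. It lay near the 3' end of this plus-strand gene, which runs from 107436365 to 107558595 and has 11 annotated start sites. The matrix genes Epyc and Snorc were 2 of the 3 without a peak. In the surface ectoderm list 18 of 20 genes were marked (Fisher's exact test, adjusted p = 0.0380), with Esrp2 at 4.43 kb and Wnt10a at 4.13 kb, and Krt15 and Rab25 without a peak. The ectodermal regulator Trp63 had a weak peak of 4.86-fold whose domain measured 1.92 ± 2.07 kb in the replicates (SD, n = 2). The ectoderm call was lost at a −log10 q of at least 5 and with a 500 bp window, with 17 of 20 marked and differences of 18.4 and 18.6 percentage points where the main setting had 23.1. In the myogenic list 15 of 25 genes were marked (exact test, adjusted p = 0.568), and Myod1, which commits cells to muscle, had a fold of 7.12 over 2.99 kb. The tendon and connective tissue list had 15 of 18 (exact test, adjusted p = 0.247), the endothelial list 14 of 19 (adjusted p = 0.657) and the Schwann and neural crest list 12 of 18 (adjusted p = 1), with Sox10 at 12.1-fold. None of these 4 lists passed the threshold. Within CpG classes the tendon and connective tissue list was above other genes by 24.6 percentage points (exact stratified test, adjusted p = 0.0174), and on the pooled list the endothelial list was by 27.0 points (Fisher's exact test, adjusted p = 0.0151).

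Among genes of other tissues, the neuronal list stood apart. There 24 of 25 genes were marked (adjusted p = 0.00176, Fisher's exact test), including the forebrain regulators Foxg1 with 2.56 kb and 16.6-fold, Emx1 with 5.33 kb and Dlx1 with 5.11 kb, and Neurod6 alone had no peak. The cardiac list had 10 of 18 (exact test, adjusted p = 0.364), with Nkx2-5 at 3.33-fold over 0.609 kb, Hand1 at 7.25 kb and Gata6 at 4.997 kb, and no peak at Mybpc3 and Myh6. Of 24 liver and gut genes 9 were marked (exact test, adjusted p = 0.00618). Alb, the serum albumin gene, and Afp had no peak, whereas Hnf1b had a domain of 3.88 kb and Foxa3 had 70.5-fold over 3.96 kb in a promoter window that it shares with Sympk. In the eye and photoreceptor list 8 of 20 were marked (exact test, adjusted p = 0.0204), with Vsx2 and Pax2 at 2.81 and 2.30 kb and none at Crx and Cryaa. In the germ cell list 2 of 26 were (exact test, adjusted p = 1.28e-09), Dazl at 0.867 kb and Tdrd1 at 0.529 kb, with none at Acrv1 and Ddx4.

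Blood and mature bone genes were mostly unmarked. Of 19 macrophage and immune genes, Lck and Cd68 had a promoter peak (Fisher's exact test, adjusted p = 1.43e-06), and Adgre1 and Aif1 did not in the replicated list. Of 17 erythroid genes 6 were marked (exact test, adjusted p = 0.0129), with Tal1 at 4.64 kb and Epor at 3.07 kb, and none at Alas2 or Ermap. The Tal1 domain was narrower in the replicates, at 2.82 ± 0.954 kb (SD, n = 2). Of 15 mature bone genes 5 were marked (exact test, adjusted p = 0.0143), among them Sp7, the osteoblast regulator, with 8.06-fold, and Sost with 3.19-fold, while the osteocalcin genes Bglap and Bglap2 had none. Within classes of promoter CpG content the calls for bone, erythroid, liver and eye genes ended, with adjusted p of 1, 1, 0.117 and 0.246 by an exact stratified test. The erythroid call also ended among genes with promoter windows free of other genes (exact test, adjusted p = 0.0514), with the same 6 of 17 marked and a difference of −26.9 percentage points where the main setting had −31.6. Receptor and barrier families were almost without H3K4me3: 3 of 1093 olfactory receptor genes (Olfr94, with 41.9-fold, and Olfr1033 among them), 1 of 327 vomeronasal receptor genes (Vmn1r4, whose window overlaps another gene's), 1 of 57 keratin-associated protein genes (Krtap17-1) and 0 of 42 beta-defensin genes had a promoter peak. Adjusted p was at most 3.28e-20 for each of these 4 families, and Olfr1, Olfr10, Vmn1r1, Vmn1r10, Krtap1-3, Krtap1-4, Defb1 and Defb10 were among the unmarked members.

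Genes used by nearly all cells were marked throughout. All 30 housekeeping genes (adjusted p = 1.65e-05), all 17 genes of the H3K4 enzyme list (adjusted p = 0.00240) and all 78 genes of the mitochondrial ribosome (adjusted p = 1.67e-13) had a promoter peak, as did 80 of 83 ribosomal protein genes (adjusted p = 2.65e-10, Fisher's exact test). The H3K4 enzyme list holds genes of H3K4 methyltransferases, of subunits of their complexes and of H3K4 demethylases. Actb lay at 74.3-fold in 3.87 kb (4.70 ± 1.34 kb in the replicates, SD, n = 2) and Gapdh at 76.7-fold in 6.05 kb (5.13 ± 1.23 kb, SD, n = 2). Rpl10l and Rpl39l, both like-named copies of ribosomal genes, were unmarked. Of 394 genes with a Zfp symbol 348 were marked (exact test, adjusted p = 3.02e-22), and Zfp345 and Zfp352 were not. The calls for HoxA and HoxD, housekeeping, H3K4 enzyme and ribosomal protein genes ended within CpG classes, with adjusted p of 0.502, 0.0624, 1 and 0.395. With 1 start site per gene the calls for HoxB and HoxC, chondrogenic, surface ectoderm, neuronal and H3K4 enzyme genes ended at adjusted p of 0.109, 0.0504, 0.0788, 0.0528 and 0.0567 (exact test), with differences of 20.9, 19.5, 21.7, 20.7 and 24.9 percentage points where the main setting had 33.1, 22.8, 23.1, 29.1 and 33.1.

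**Figure D3:**
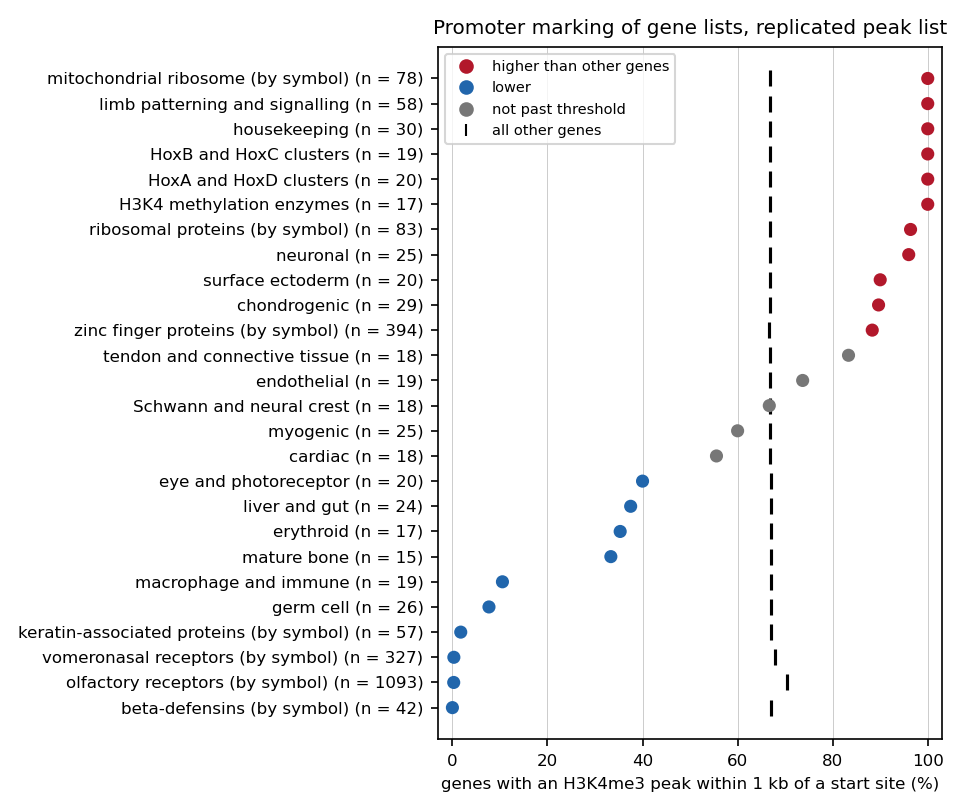
Share of the genes in each list with an H3K4me3 peak of the replicated list within 1 kb of a start site (x axis, percent; y axis, lists with their number of genes). Red and blue points are lists above and below all other protein-coding genes at an adjusted p under 0.05 and grey points are the rest; black ticks are the other genes. Shares run from 0% for beta-defensins to 100% for 6 lists, limb patterning among them.

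Limb patterning, cartilage and connective tissue genes lay in wide domains. Against random lists of marked genes, 8 of 20 lists had wider domains and 2 had narrower ones. The HoxA and HoxD genes had a median of 48.6 kb, with 20 genes in 8 domains, so most of these widths are not independent. With each domain counted once their median was 4.44 kb against 2.21 kb for random lists (permutation test, adjusted p = 0.00267), and with only touching peaks joined the median per gene was 8.53 kb. Limb patterning genes had 7.20 kb, also with each domain counted once, tendon and connective tissue genes 4.80 kb, with Osr2 at 10.2 kb and Tcf4 at 10.001 kb, and chondrogenic genes 4.44 kb. Tcf4 was entered by symbol, which is a gene on chromosome 18, and its standing as a connective tissue marker was not checked. Adjusted p was 8.0e-04 for each of these 4 lists, from a raw p of 2e-04, the smallest that 10000 random lists can give (permutation test, two-sided). By the same permutation test, smaller excesses were seen for HoxB and HoxC genes (3.57 kb, adjusted p = 0.00286), H3K4 enzyme genes (3.08 kb, adjusted p = 0.0480; Setd1b 14.2 kb, Kmt2d 5.96 kb), housekeeping genes (3.02 kb, adjusted p = 0.0105; Chmp2a 6.74 kb, Eef2 6.46 kb) and ribosomal protein genes (2.81 kb, adjusted p = 0.00133; Rpl18 7.86 kb, Rps11 7.72 kb). The Setd1b domain also covers another gene's promoter.

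Neuronal genes, nearly all of them marked, had a median width of 2.25 kb (permutation test, adjusted p = 0.931), and myogenic genes had 2.82 kb (adjusted p = 0.157). With gaps of up to 3 kb myogenic genes were wider, at 3.54 kb (permutation test, adjusted p = 0.0332). In that setting liver and gut genes were wider too, at 3.89 kb (permutation test, adjusted p = 0.045). Zfp genes were narrower at 1.91 kb (adjusted p = 8.0e-04), and the 10 marked cardiac genes were narrower at 1.46 kb (adjusted p = 0.0240, permutation test). Among Zfp genes, Zfp503 and Zfp36 nevertheless lay in domains of 14.6 and 13.9 kb. The Zfp36 domain also covers another gene's promoter and measured 8.24 ± 4.95 kb in the replicates (SD, n = 2). Mitochondrial ribosome genes had 2.07 kb (permutation test, adjusted p = 0.157), with Mrps34 at 5.38 kb and Mrps18b at 5.33 kb. Against CpG-matched random lists, with 2.335 kb, they were narrower (permutation test, adjusted p = 0.0385). The H3K4 enzyme call held in 3 of 9 alternative settings and the cardiac call in 6 of 9, and with gaps of up to 3 kb cardiac genes were wider, by 2.86 kb. The H3K4 enzyme excess over random lists was 0.807 kb in the main setting. Where its call ended, the excess ran from 0.452 kb against CpG-matched lists to 0.841 kb with gaps of up to 3 kb. The HoxB and HoxC call ended when only touching peaks were joined, with a difference of −0.06 kb from random lists, and with each domain counted once (2.74 kb, permutation test, adjusted p = 0.167). The housekeeping call ended at a −log10 q of at least 5 (2.77 kb, permutation test, adjusted p = 0.0622). The ribosomal protein call ended against CpG-matched random lists, with 2.81 kb against 2.557 kb (permutation test, adjusted p = 0.123).

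**Figure D4:**
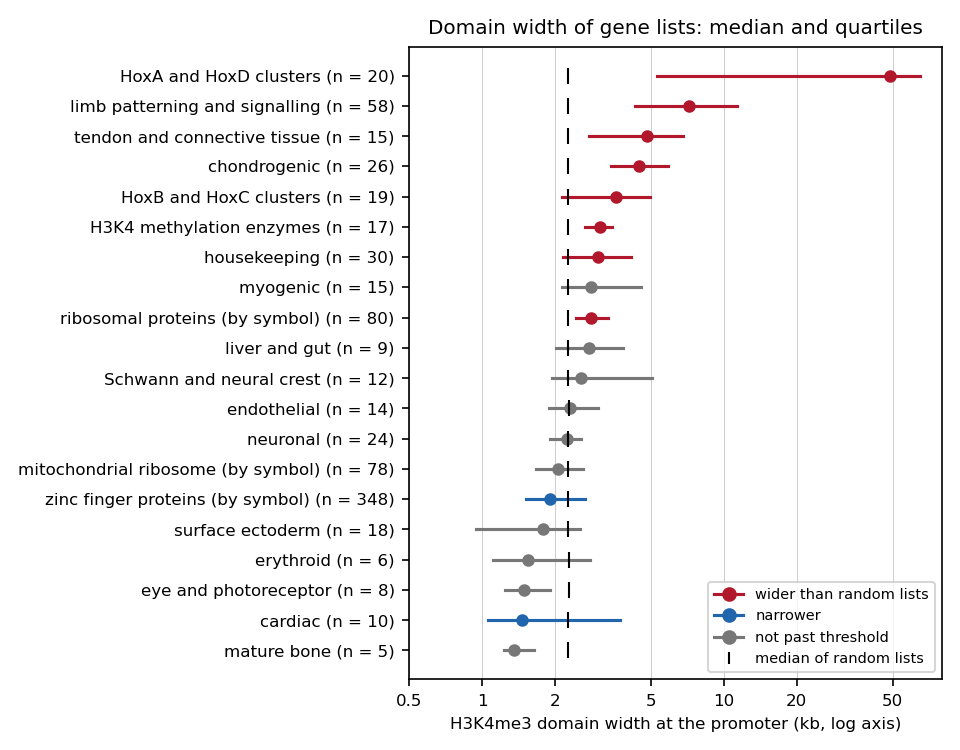
Width of the H3K4me3 domain at the promoters of the marked genes of each list (x axis, kb, log scale; y axis, lists with their number of marked genes). Points are medians, lines run from the lower to the upper quartile, black ticks are the median of random lists, and red and blue mark lists wider and narrower than random lists at an adjusted p under 0.05. With shared domains counted for each gene, HoxA and HoxD genes lie at 48.6 kb and limb patterning genes at 7.20 kb, with random lists near 2.27 kb.

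Promoter marking followed CpG content. Of 11236 genes with a CpG-rich start site, 11139 (99.1%) had a peak, and of the 10702 others 3537 (33.0%) had one. The odds ratio was 233 in the replicated list, 232 in replicate 1 and 222 in replicate 2, and Fisher's exact test, two-sided, gave a p of 0 at machine precision. Among the genes named, Tbx5, Tbx4, Prrx1, Fgf10 and Shh lacked a CpG-rich start site by this definition and were marked, and Ddx4 had a CpG-rich start site and was not.

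On the X chromosome 494 of 948 protein-coding genes (52.1%) had a promoter peak, against 14178 of 20807 autosomal genes (68.1%). The odds ratio was 0.509 (Fisher's exact test, two-sided, p = 1.39e-23), and it was 0.501 in replicate 1 and 0.507 in replicate 2. Within CpG classes no difference passed the threshold. Among CpG-rich genes 98.2% on the X and 99.2% on autosomes were marked (odds ratio 0.457, Fisher's exact test, p = 0.0894), and among the others 33.0% and 33.6% were (odds ratio 0.972, p = 0.767). The odds ratio stratified by class was 0.955 (exact test, p = 0.586), a setting chosen after the data were examined. Without the olfactory, vomeronasal, keratin-associated and defensin families the unstratified odds ratio was 0.399 (Fisher's exact test, p = 1.06e-40). On the Y chromosome 4 of 183 genes had a peak.

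Arid1a, a subunit of a chromatin remodelling complex, had the highest promoter fold of the replicated list, 88.7, in a domain of 8.78 kb (8.74 ± 0.0262 kb in the replicates, SD, n = 2). Syncrip, an RNA-binding protein gene, had 86.8-fold, Kdm5b, which encodes an H3K4 demethylase, 85.9, Ssbp3 85.7 and Msl1 85.5. The widest domains without a protein-coding start site lay at noncoding genes. The first, on chromosome 5 from 119796328 to 119808116, spanned 11.8 kb (11.5 ± 1.00 kb, SD, n = 2) at 1700021F13Rik, between the domains of Tbx3 and Tbx5. The next spanned 10.2 kb at Dleu2 on chromosome 14 (7.56 ± 3.66 kb, SD, n = 2) and 9.93 kb at C230035I16Rik on chromosome 13 (9.55 ± 0.128 kb, SD, n = 2).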

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

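The alternatives were set before the data were examined, except matching random lists on start sites, added before the widths were tested, and stratifying the X comparison by CpG class and all settings of the fold test, which were chosen after the results were seen. Of the alternative values for the main results 78 kept their side of the threshold, their count within 1.5 times or their value within the replicate spread, 24 moved beyond that spread, 4 weakened and 2 strengthened. Among these results, the correlation of promoter fold and the odds ratios for CpG content and the X chromosome have a direction. It held in all of their alternatives. The counts and shares have no direction that could reverse. With 50% of both peaks required, 69.4% of replicate 1 and 70.5% of replicate 2 peaks were shared, and with 50% of either 77.2% and 78.6%. At a −log10 q of at least 2 it was 85.7% and 87.5%, and at 5 or more 93.9% and 95.1%, since weak peaks drop out. The replicated list then covered 39.2 Mb. With 50% of both peaks required, 85.9% of its peaks overlapped both replicates. Marked genes ranged from 67.2% to 67.3% on a single replicate, and were 67.8% on the pooled list, 66.6% at −log10 q of 5 or more, 66.5% and 67.5% with windows of 500 bp and 2 kb, and 63.3% with 1 start site per gene. The share of peaks at protein-coding start sites was 55.1% to 55.9% on a single replicate, 51.8% on the pooled list, 66.4% at −log10 q of 5 or more, 60.6% and 67.8% with the 500 bp and 2 kb windows, and 51.8% with 1 start site per gene. Lists with more promoter peaks fell from 11 to 6 with 1 start site per gene, and lists with fewer from 10 to 6 when stratified by CpG class. The X odds ratio moved from 0.509 to 0.955 when stratified by CpG class and to 0.399 without 4 symbol families. Lists with narrower domains numbered 2, and 3 to 4 on a single replicate, 4 with gap 0 and 1 with a gap of 3 kb. For single lists, the HoxB and HoxC width difference turned to −0.06 kb with gap 0 and the cardiac one to 2.86 kb with a gap of 3 kb. The cause was not tested beyond what each setting removes. The weakest 10% of each replicate's peaks, at a median of 2.62-fold, were mostly not shared.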

Other observations

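The tests of promoter fold per list, the comparisons between pairs of lists, the depth test and the CpG tests for subsets of lists were chosen, with their bounds, after the results were seen. The 58 limb patterning genes, with domains of 7.20 kb, had a median fold of 41.1, below the 51.9 of random lists of marked genes (permutation test, adjusted p = 0.0060 over 20 lists), a call that held in 5 of 5 alternatives. Housekeeping genes had 62.8-fold in domains of 3.02 kb, and limb genes differed from these by −21.8 in median fold (permutation test, adjusted p = 4e-05 over 6 comparisons of pairs of lists) and by 4.18 kb in median width (adjusted p = 1.35e-04). Neuronal genes had 18.3-fold and 2.25 kb, a width close to the 2.27 kb of random lists, and limb genes exceeded them by 22.8 in median fold (permutation test, adjusted p = 4e-05) and by 4.95 kb in median width (adjusted p = 2.76e-04). HoxA and HoxD genes had a median of 54.1-fold and HoxB and HoxC genes 9.86-fold (permutation test, adjusted p = 4e-05), although every gene of both lists is marked. Several of these genes take their fold from a shared peak, as Hoxa9, Hoxa10, Hoxa11 and Hoxa13 do at 77.0-fold, so this p-value is too small. The comparison was not repeated with each peak counted once. In all, 14 of 20 lists had lower and 4 had higher fold than random lists, the higher ones being housekeeping, H3K4 enzyme, ribosomal protein and mitochondrial ribosome genes. Against CpG-matched lists 11 were lower, the mature bone, tendon and erythroid calls having ended, and the H3K4 enzyme call ended while Zfp genes became higher. The tendon call also ended without replicate 1 and the mitochondrial ribosome call without replicate 2. Fold is a value at the summit over a mixed tissue, and the share of cells carrying the mark was not measured.

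Away from protein-coding start sites 10.6% of 7743 long noncoding RNA genes had a peak at a start site in the replicated list (11.1% in each replicate), as did 2.00% of 13069 pseudogenes. Among genes chosen after their values were seen, Xist, the RNA that silences an X chromosome in females, had 17.1-fold over 3.62 kb in these pools of both sexes. The imprinted genes H19, Meg3, Airn and Kcnq1ot1 had 32.1, 30.3, 36.9 and 32.4-fold. Malat1 lay in a domain of 9.60 kb at 52.5-fold. In the Hox clusters Hottip, beside Hoxa13, shared the 64.7 kb HoxA domain and had the same 77.0-fold as Hoxa11 in the replicated list, but 51.0 and 53.5-fold in the replicates, where Hoxa11 had 64.1 and 71.1, and Hotair, in HoxC, had 8.09-fold over 6.19 kb.

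Of the peaks of replicate 1, 19.9% were not in the list of replicate 2, and 18.4% the other way round. Replicate 2 is the shallower only by the background read back from its folds, but in either list at least 18.4% were unshared, which argues against a depth difference between the replicates as the whole cause. Peaks near the calling threshold are a candidate explanation: 0% of the strongest 10% of peaks were unshared, and unshared peaks had at most 0.146 times the median fold of shared ones. Whether such weak sites carry H3K4me3 in few cells or are noise stays open. No biological explanation was tested for this or the next patterns, since the design has 1 group.

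Some lists had more and some fewer promoter peaks than other genes, and promoter CpG content could produce both. Within CpG classes 7 of the 11 higher lists and 6 of the 10 lower lists stayed past the threshold, which argues against the CpG class as the whole cause for those lists. Genes were split only into CpG-rich and others, so differences in CpG content within a class could still contribute and were not tested. Differences shrank from 33.2 to 11.2 percentage points for limb patterning and from 33.2 to 9.39 for mitochondrial ribosome genes. They shrank from −56.4 to −26.0 for macrophage and from −70.1 to −36.5 for olfactory receptor genes. The change was small for HoxB and HoxC (33.1 to 32.2) and Zfp genes (21.8 to 19.6). Differences rose for chondrogenic (22.8 to 24.7) and surface ectoderm genes (23.1 to 27.2). Of the HoxA and HoxD, housekeeping, H3K4 enzyme and ribosomal protein genes 19 of 20, 27 of 30, 17 of 17 and 77 of 83 lie in the CpG-rich class, which is 99.1% marked, so few members could show an excess; 4.17, 7.49, 0.865 and 2.04 percentage points were left without a call, and the excess cannot be told apart from CpG content. For mature bone and erythroid genes the difference shrank from −33.6 and −31.6 to −4.13 and −1.65 percentage points, as CpG content as the source would give. These lists hold 15 and 17 genes, with 1 gene of each in the CpG-rich class. A remaining difference could therefore be missed, and CpG content is not shown to be the only source. For liver and gut and for eye genes −14.8 and −12.9 points were left, without a call, and the explanation stays open.

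Limb, cartilage and connective tissue genes lay in wide domains, and 3 technical sources could widen them. Against random lists matched on promoter CpG content 6 of the 8 wider lists stayed past the threshold, against lists matched on the number of annotated start sites per gene 7 did, and with members sharing one domain counted once 7 did, which argues against each as the whole cause of the call in the lists that stayed. With each domain counted once the HoxA and HoxD excess over random lists shrank from 46.3 to 2.23 kb with the call kept, and the HoxB and HoxC excess shrank from 1.30 to 0.536 kb and its call ended. With only touching peaks joined, and shared domains still counted for each gene, the HoxA and HoxD excess was 6.37 kb. Most of that excess thus depends on joining peaks across gaps and on counting a shared domain for each gene. The H3K4 enzyme excess of 0.807 kb was 0.745 kb against start-site-matched lists, hardly smaller, with the call ended at adjusted p = 0.0512 (permutation test), and 0.452 kb without a call against CpG-matched ones, where the ribosomal protein excess went from 0.541 to 0.254 kb without a call. How the caller splits or joins peaks stays open, because signal tracks were not analysed, and the hypothesis that wide domains may mark regulators of the tissue would need a second tissue.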
